A study of Mus musculus with 24 samples.

How the data were processed

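RNA of 24 sorted mouse cell samples was measured, each on 1 Agilent single-colour Cy3 array of design 028005. Per the labels' protocols, cells were isolated by flow cytometry and lysed directly. Polyadenylated RNA was captured on magnetic beads, copied with tagged random and oligo(dT) primers, amplified by PCR and labelled with Cy3 (the SuperAmp procedure), so the signals come from amplified cDNA of few cells. The labels placed the samples in 8 groups. Thymocytes came from a thymus heterozygous for the Foxn1 mutation, called wt here: DN3, the CD4 and CD8 double-negative stage (n = 3), DP, the CD4 and CD8 double-positive stage (n = 3), SP4, CD4 single-positive (n = 3), and SP8, CD8 single-positive (n = 3). DP cells (n = 4) and IgM-negative B cells (n = 2) came from transgenic thymus lacking Foxn1, called tg here; the labels used here do not name the transgenes. IgM-negative (n = 3) and IgM-positive (n = 3) B cells came from wild-type fetal liver. A label of the SP4 samples also names SP8, and their group was taken from the title. The labels do not say whether the tg DP and tg B cells came from the same transgenic line. Replicates are named by the numbers of their titles, of which some are shared (3 and 3A, and 6, 6A and 6B), so that DP may hold 2 wt and 2 tg samples.

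Per the file headers, the deposited spot values are intensities from Feature Extraction 10.7.3.1 on a G2505C scanner: a processed signal (background-subtracted and detrended by that program), mean and background signals, and flags for saturation, uniformity and signal well above background. The deposited series matrix holds the authors' log2 values. Each of its columns had a median of 7.93 and kept the order of that array's own log2 signals, so the scale was log2, the values were made equal in distribution between arrays, and genes were not centred; the program that made it is not given in the sources used here. It served as an alternative.

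Control spots (3671 of 62976 per array) were left out, 238 non-uniform values were set to missing, no spot was saturated, and spots of 1 probe were averaged, giving 55681 probes. Gene names came from the accession in the spot files through a reference gene table for 26762 probes, from the symbol for 3819, from a synonym for 639 and from the description for 4; 24457 probes kept the name in the file, which can be old. In all 34787 names resulted. Coordinates are those of the array annotation, build mm9; exon or untranslated-region positions of the probes are not given in the sources used here. The main value was log2 of the processed signal minus the array's 75th percentile of it. A gene was represented by its brightest probe over all arrays and kept if any of its probes was well above background on every array of at least 1 group. This filter removed little: 95.2% of probes passed, leaving 33553 genes.

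Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 24 arrays with group means and no covariate, so every comparison shared 1 estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were tg against wt DP, tg thymic against fetal liver IgM-negative B cells, IgM-positive against IgM-negative fetal liver B cells, DP against DN3, SP4 and SP8 against DP, SP4 against SP8, and the difference of the effects in both tg comparisons. All of these, 35 gene lists (579 of 594 genes measured), the rule for named genes and most alternatives were chosen before the data were examined. A comparison of the 12 wt thymocyte arrays with the 6 fetal liver B arrays was added after the data were examined, and which lists a comparison is about was written down after the list results had been seen. Lists were tested against all other genes with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, leaving out 82 genes with a missing value; p-values were adjusted over the lists within a comparison. Stage and lineage signatures were the 200 genes with the strongest differences between cell types, taken without the arrays of the comparison they served.

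Named genes were up to 8 rises and 8 falls past the threshold whose groups did not overlap and that carry a gene symbol, up to 4 members with the strongest statistic in each list that passed or that the comparison is about, and 12 fixed label and niche genes. Some genes that this rule selects are not reported here. A probe not well above background on any array of a group has only a bound there. Its fold is given as "at least": the brighter group's mean against, per array of the dimmer group, the higher of the probe's own value and the lowest spot signal well above background. Such a bound holds for the measured means only and makes no allowance for the spread between arrays. Other probes were well above background on part of a group: Lig4 on 2 of 3 wt DP and 1 of 3 IgM-positive arrays, Erg and Rag2 on 1 of 3 IgM-positive arrays, and Il7r on 1 of 3 wt DP arrays. S1pr1 was so on 2 of 3 wt DP arrays, Gzmb on 2 of 3 SP4 arrays, Il2rg on 3 of 4 tg DP arrays, Satb1 on 11 of 12 thymocyte arrays, and Tcf7 and Satb1 on 5 of 6 and Trac on 3 of 6 fetal liver B arrays.

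The arrays lay on 4 slides. Slide 1 held tg DP 4, SP4 11 and IgM-positive 19. Slide 2 held the wt DP arrays, tg DP 6, 6A and 6B, and DN3 7. Slide 3 held DN3 8 and 9, SP4 10 and 12, and the SP8 arrays. Slide 4 held the IgM-negative fetal liver arrays, IgM-positive 20 and 21, and both tg B arrays. The wt DP arrays shared no slide with SP4 or SP8. Alternatives were normexp background correction, quantile and median scaling, the series matrix, no filter on dim probes and a filter on 2 arrays, the slide as a fixed or random block, a fit of the compared groups only, a trended and robust fit, the mean over probes, a 2-fold minimum, averaging samples whose titles share a number, leaving out each array, an estimated correlation and larger signatures. Added after the data were examined were array quality weights, leaving out the 3 arrays that stand apart, testing each probe, the probe of lowest GC content and arrays of 1 slide only. The test and list steps were first tested on simulated data of 33471 genes. Of 200 changed genes, 67 were changed by 2 on the log2 scale, and 59.7% of these were called at the size of the tg against wt DP comparison and 47.8% at that of the tg B comparison, so small groups did not by themselves prevent all calls. For changes of 1 these shares were 20.9% and 17.9%. The simulated noise was independent between genes and equal across arrays, whereas the real arrays had quality weights of 0.25 to 3.14, so fewer calls may be expected from them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.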

Results

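The series profiled blood progenitors of thymic and fetal niches on 24 arrays, asking how the niche in which they develop shapes them. Thymocytes of 4 stages from heterozygous thymus, DP thymocytes and B cells of a transgenic thymus without Foxn1, and B cells of fetal liver were compared. Values below are log2 signals relative to the array's 75th percentile, with SD, and differences are on the log2 scale with the SE of limma's fit. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Between 87.6% and 96.7% of probes were well above background, except on tg B array 23, where 80.7% were and the median processed signal was 125 against 208 to 314 on the others. On the first principal component, which carried 18.2% of the variance, tg B 23 lay at 239, IgM-positive 21 at 116 and tg DP 4 at 47.1, and the other arrays between -60.3 and 23.7.

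Foxn1, the transcription factor of thymic epithelium that the mutation targets, measured 0.25 ± 0.11 in wt DP (n = 3), -0.20 ± 0.30 in DN3 (n = 3), 0.02 ± 0.40 in SP4 (n = 3) and -0.13 ± 0.10 in SP8 (n = 3). It measured 0.02 ± 0.16 in tg DP (n = 4), -0.40 ± 0.74 in tg B (n = 2), -0.31 ± 0.17 in IgM-negative (n = 3) and -0.48 ± 0.28 in IgM-positive fetal liver B cells (n = 3). Lymphocytes are not where Foxn1 acts, and the part of the gene that the mutation removes is not given in the sources used here, so its level checks no label. For genes of the niche, group means spanned -1.44 to -0.96 for the chemokine Cxcl12, 3.96 to 4.27 for Ccl25, -0.48 to 0.56 for the Kit ligand Kitl and 0.92 to 1.33 for the Notch ligand Dll4. Surface genes of the sorts separated the groups unevenly. Cd4 was 3.57 ± 0.06 in SP4 and 3.39 ± 0.06 in SP8 on its brightest probe, but its other probe went the other way (2.26 and 2.35). The T cell receptor component Cd3e lay between 0.46 and 0.84 in every group, B cells included. Ighm, the IgM heavy chain, was 0.88 ± 0.75, 0.89 ± 0.33 and 1.77 ± 2.00 in IgM-negative, IgM-positive and tg B cells and 0.08 to 0.44 in the T groups. Il2ra, carried by DN3 cells, was -2.88 ± 0.41 there and -1.76 ± 0.24 in tg B. Cd8b1, a CD8 chain, went against the labels, with -2.14 ± 0.54 in SP4 and -3.56 ± 0.65 in SP8, without passing (adjusted p = 0.785). The brightest Cd8a probe was at -0.95 ± 0.37 in SP4 and -0.96 ± 0.44 in SP8. A second Cd8a probe, chosen after its values were seen (chromosome 6, 71323885 to 71323944, mm9), measured -0.43 ± 0.28 in SP8 and -4.35 ± 1.15 in SP4, a difference of -3.93 ± 0.90 (SE, adjusted p = 0.487).

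Thymocytes and fetal liver B cells were compared to see how far lineage genes separate the groups (12 against 6 arrays), a comparison added after the data were examined. Tcf7, a transcription factor needed for T cell development (chromosome 11, 52066114 to 52066173, mm9), rose in thymocytes by 4.29 ± 0.64 (-0.48 ± 1.63 against -4.77 ± 1.42, adjusted p = 0.0187). The T cell receptor beta constant gene Trbc2 (chromosome 6, 41497058 to 41497622) rose by 2.54 ± 0.39 (2.12 ± 0.82 against -0.42 ± 0.42, adjusted p = 0.0187), and for both genes all 12 thymocyte arrays lay above all 6 B cell arrays. Falls were smaller, with all 12 thymocyte arrays below: the secreted guidance protein Ntn1 by 0.94 ± 0.16 (adjusted p = 0.0267), Fbxo17 by 0.72 ± 0.10 and Zfp446 by 0.68 ± 0.10 (adjusted p = 0.0187 each). Abcb8, Samd8, Tnfrsf22 and Ankrd12 fell by 0.70, 0.63, 0.61 and 0.58. The T lineage list rose, with 16 of 20 members higher (median 0.54, adjusted p = 0.0095, and adjusted p = 0.380 with an estimated correlation). Satb1, a chromatin organiser, was at 3.31 ± 0.70 (adjusted p = 0.055) and Bcl11b, a T commitment factor, at 1.23 ± 0.33 (adjusted p = 0.112). The B lineage list fell, with 17 of 20 members lower (median -0.30, adjusted p = 0.0014, and adjusted p = 0.270 with an estimated correlation). Cd79a, a B cell receptor component, was at -1.49 ± 0.46 on its brighter probe and 0.06 ± 0.32 on its other probe, and the B lineage regulator Pax5 at -0.38 ± 0.12. Genes of MHC class II, which presents antigen to CD4 cells, fell too, with 9 of 10 lower (median -0.37, adjusted p = 0.0022, and 0.0355 as the adjusted p with an estimated correlation). Adjusted over the list alone, 4 of them passed, and 8 T lineage genes passed upward and 2 downward. Antigen receptor loci did not pass as a list (adjusted p = 0.834, median -0.07, mean 0.53). Trac, the alpha constant gene, was at 2.66 ± 0.71 and Trbc1 at 0.87 ± 0.23, while Tcra was at -0.32 ± 0.10. In all, 31 genes rose and 51 fell. By comparison, 82 rose and 103 fell with normexp, 30 and 111 with quantile scaling, and 13 and 37 with median scaling. Both lineages met only on slide 1 (1 array each), where the differences were at least 4.66 for Tcf7 (not well above background on the B cell array), 2.09 for Trbc2, 0.85 for the T lineage mean, -0.17 for the B lineage mean and -0.48 for MHC class II. With slide as a block, no list passed: T lineage turned to a median of -0.26 (adjusted p = 0.970), B lineage was at -0.28 (adjusted p = 0.789) and MHC class II at 0.03 (adjusted p = 0.789). In that fit 32 genes passed, but none of those named here: Tcf7 stood at 4.31 ± 1.18 (adjusted p = 0.220), Trbc2 at 0.31 ± 0.88 (adjusted p = 0.946) and Tnfrsf22 at 0.11 ± 0.26. Ankrd12 was the closest of the others, at -0.60 ± 0.28 (adjusted p = 0.512). The count of 82 was 0 without IgM-negative 16, IgM-negative 18 or IgM-positive 21, 1 without IgM-negative 17, 367 without IgM-positive 19 and 103 without IgM-positive 20. Among T arrays, it was 9 without DP 3A or SP8 13, 21 without DP 2 or SP8 14, 20 without DN3 9 or SP4 10, 23 without DN3 7, 48 without SP4 12 and 40 without SP8 15. The T lineage list gave adjusted p = 0.0856 without IgM-positive 19 and the B lineage list 0.0627 without IgM-positive 20.

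**Figure D1:**
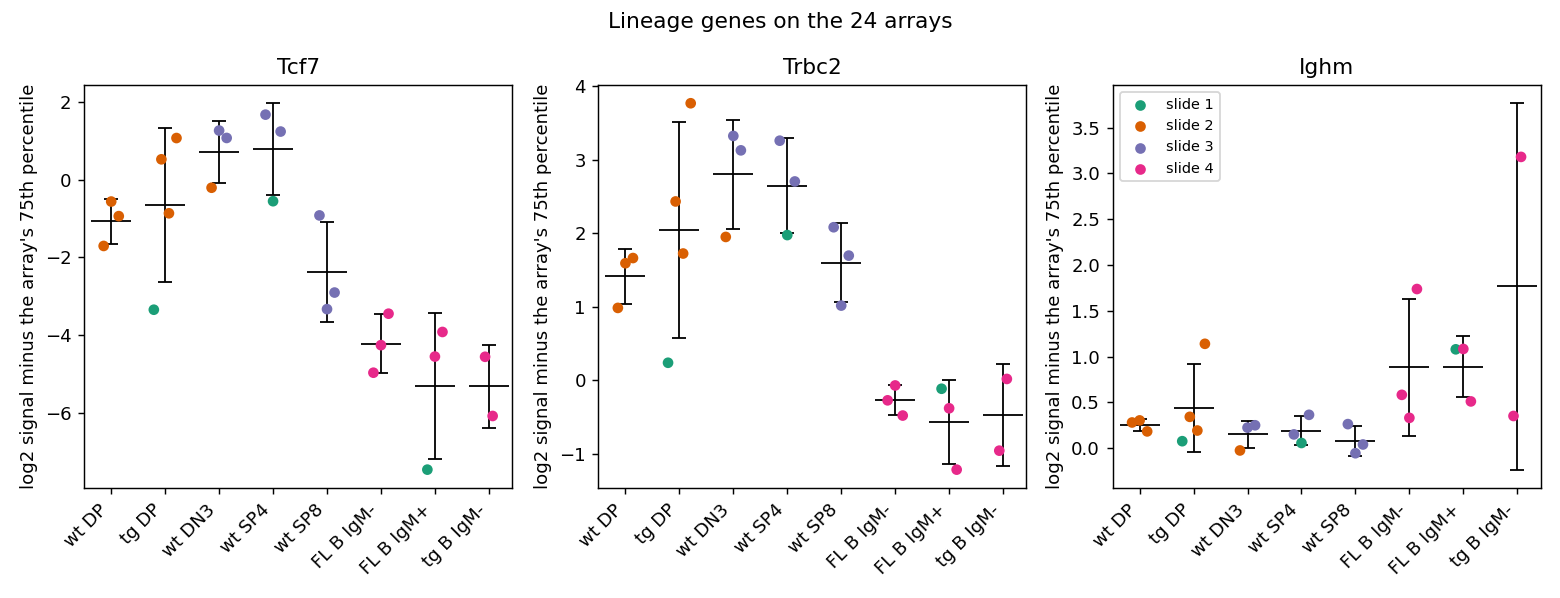
Tcf7, Trbc2 and Ighm on each array (y axis, log2 signal minus the array's 75th percentile) by group, with points coloured by slide and bars for the mean ± SD. Tcf7 averaged -0.48 in the 12 wt thymocyte arrays and -4.77 in the 6 fetal liver B arrays, whereas Ighm overlapped between groups.

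DP thymocytes that developed in the transgenic thymus were compared with those of the heterozygous thymus (4 against 3 arrays), the comparison of the same cell stage in different niches. Titles 6, 6A and 6B and titles 3 and 3A share numbers, so these arrays may be repeats and n may be 2 against 2. Genes of the recombination machinery, which assembles antigen receptor genes, rose as a list, with 10 of 12 members higher in tg DP (median 0.29, adjusted p = 0.0185). Its adjusted p was 0.743 with an estimated correlation. The DNA ligase Lig4 was at 1.78 ± 0.73 (-3.07 ± 0.69 against -4.85 ± 0.59), the hairpin-opening nuclease Dclre1c at 0.46 ± 0.23 (-0.23 ± 0.26 against -0.69 ± 0.05) and the DNA-bending cofactor Hmgb1 at 0.33 ± 0.18 (3.93 ± 0.11 against 3.59 ± 0.09), with all 4 tg arrays above all 3 wt arrays for each. Rag1, the recombinase itself, was at 0.68 ± 0.62, but at 1.35 without tg DP 4 and -0.02 with arrays sharing a title number averaged. The lists closest to the question did not pass. T lineage had 15 of 20 members higher (median 0.15, adjusted p = 0.328), with the receptor chain Cd247 at 1.43 ± 0.54 and the transcription factor Gata3 at 0.97 ± 0.48. DP stage had 12 of 16 higher (adjusted p = 0.594), with the survival gene Bcl2l1 at 1.20 ± 0.63 (-0.16 without tg DP 4, where another probe became the brightest). On the first probe tg DP 4 was at 2.33 and the other tg arrays at 1.19 to 1.46. Notch targets and pre-TCR genes did not pass (adjusted p = 0.647, median 0.03, mean -0.00), with the Notch regulator Dtx1 at -0.60 ± 0.32. Adjusted p was 0.647 for niche ligands, with Dll1 at -1.0 ± 0.38, and 0.950 for both niche signal receptors and B lineage genes, with the cytokine receptor chain Il2rg at -1.35 ± 1.16 (0.02 without tg DP 4) and the kinase Btk at -0.44 ± 0.23. No single gene passed in limma (smallest adjusted p = 0.512; 1110 genes had an unadjusted p under 0.05). Other settings gave 0 genes except array weights, with 7. On slide 2, with 3 arrays each, the recombination list differed by 0.38 (-0.95 against -1.34). The tg arrays there were 6, 6A and 6B, which may be repeats of the same sample, and the fit with slide as a block leans on them. With slide as a block it passed with a median of 0.45 (adjusted p = 0.0099), as did T lineage (adjusted p = 0.0099). The recombination list was lost when arrays sharing a title number were averaged (adjusted p = 0.486), without wt DP 3 (adjusted p = 0.161), without tg DP 6 (0.223) and with the lowest-GC probe (0.609), within a range of 0.0018 to 0.743. Without tg DP 4, when all remaining tg arrays shared title number 6, 3 lists passed.

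Stage and lineage signatures asked whether either tg population leaned to another stage. In tg DP, the 200 genes lower in T than in IgM-positive B cells rose (median 0.07, 117 higher, adjusted p = 9.2e-05, and adjusted p = 0.591 with an estimated correlation). The genes higher in T cells and those higher in DN3 than in SP cells did not pass (adjusted p = 0.458 each, median -0.10 for the latter), nor did those lower in DN3 (adjusted p = 0.321, test upward with a median of -0.03; with quantile scaling adjusted p = 0.0019 and a median of 0.14). In tg B cells against IgM-negative fetal liver cells, genes higher in T cells fell (median -0.73, 52 of 200 higher, adjusted p = 8.3e-05, and adjusted p = 0.204 with an estimated correlation). Genes lower in T cells rose (median 0.05, 108 of 200 higher, adjusted p = 0.0067, and adjusted p = 0.344 with an estimated correlation); with 400 genes the median was -0.06 (adjusted p = 0.0847). With quantile scaling these medians were -0.30 (71 of 200 higher, adjusted p = 0.0017) and 0.19 (139 of 200 higher, adjusted p = 2.3e-05), and the median of all genes in this comparison was -0.21 with the main scaling and -0.04 with quantile scaling. The arrays tg B 23, tg DP 4 and IgM-positive 21, the last 1 of those the lineage signatures were taken from, stood apart on the first principal component (239, 47.1 and 116). On a T to B score with genes picked without the array, tg DP 4 lay on the B side (-0.03). The arrays tg DP 6, 6A and 6B lay on the T side (0.75, 0.72 and 0.64). The signatures were not tested without tg DP 4. Correlations of an array with the mean of a group, computed across genes, which are not independent replicates, spanned 0.852 to 0.977. The lowest was that of the 2 tg B arrays with each other. With the other groups, tg B 22 correlated at 0.919 to 0.935 and tg B 23 at 0.875 to 0.886. Of 24 arrays, 16 were closest to a group of their own lineage and 2 to their own group. Each tg DP array was closest to IgM-negative fetal liver B cells (0.9222, 0.9615, 0.97705 and 0.9345 for 4, 6, 6A and 6B). With wt DP these values were 0.9177, 0.9598, 0.97686 and 0.9305. The arrays wt DP 3 and DN3 8 were also closest to IgM-negative fetal liver B cells.

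IgM-negative B cells of the transgenic thymus were compared with those of fetal liver (2 against 3 arrays), the same phenotype in different tissues; age and genotype differ along with the tissue. Igf1, a growth factor (chromosome 10, 87378456 to 87378515, mm9), rose by 0.91 ± 0.17 (1.34 ± 0.13 against 0.43 ± 0.09, adjusted p = 0.0475), with another of its 5 probes at -0.58. Supt16, a subunit of the histone chaperone FACT (chromosome 14, 52780507 to 52780566), fell at least 7.1-fold (-7.60 ± 0.21 against -2.46 ± 0.97, adjusted p = 0.0018). Anxa1, a phospholipid-binding protein (chromosome 19, 20449722 to 20449781), fell at least 21.9-fold (-7.54 ± 0.19 against -0.84 ± 0.20, adjusted p = 0.0018); its other probe differed by -0.93. The lysosomal protein Laptm4a (chromosome 12, 8943520 to 8943579) fell by 4.52 ± 0.75 (-4.47 ± 0.04 against 0.04 ± 0.88, adjusted p = 0.033). Sirpb1b and the vomeronasal receptor Vmn1r4 fell at least 6.0-fold and 5.0-fold (adjusted p = 0.0489 and 0.0284). Ablim1 fell at least 19.2-fold (adjusted p = 0.0475). On the tg arrays the tested probes of Supt16, Anxa1, Sirpb1b, Vmn1r4 and Ablim1 were not well above background. Ccdc7b fell by 3.79 ± 0.74 and the E-protein Tcf12 by 3.79 ± 0.70, each well above background on 1 of the 2 tg arrays. Another probe stood at 1.05 for Ablim1 and for Ccdc7b, and the lowest-GC probe at -0.54 for Tcf12. In all, 6 genes rose and 42 fell. Under other scalings, 6 rose and 4 fell with normexp, 4 and 7 with quantile scaling, and 6 and 8 with median scaling. The median of all genes was -0.21 with the main scaling, 0.09 with median scaling, -0.04 with quantile scaling and -0.07 with normexp, so single changes stand on a general shift of that size. No list passed. B lineage had 17 of 20 members lower (median -0.73, adjusted p = 0.492, 1 passing when adjusted over the list alone). Cd79a was at -3.63 ± 0.84 (-3.29 ± 2.12 against 0.34 ± 1.15, adjusted p = 0.0933), with its other probe at -0.63 (-1.92 against -1.29), but the inhibitory receptor Cd22 at 0.45 ± 0.16. Of the pro-B and pre-B genes, 13 of 20 were lower (adjusted p = 0.850), with the stem cell factor receptor Kit at 1.69 ± 0.45 and the transcription factor Erg at least 8.7-fold lower (-7.49 ± 0.12, not well above background, against -2.17 ± 1.68). Niche signal receptors (adjusted p = 0.881) included Il2rg, at least 5.9-fold lower (-7.55 ± 0.17 against -2.74 ± 0.95), and Notch3 at -1.78 ± 0.57. Fetal haematopoiesis genes had 10 of 12 members lower (adjusted p = 0.850), with the imprinted RNA H19 at -0.74 ± 0.39 and Plagl1 at 0.56 ± 0.20. T lineage genes had 13 of 20 lower (median -0.46, adjusted p = 0.850). All 5 arrays lay on slide 4. Fitted alone, they gave 0 calls, as did a fit of these groups only and array weights, while slide as a block gave 70 but not Sirpb1b (adjusted p = 0.0622) or Tcf12 (adjusted p = 0.0530). Of the 48 calls, the count was 5855 without tg B 22 and 9 without tg B 23, where the lone tg array is assumed to vary like the other groups. It was 7, 6 and 8 without IgM-negative 16, 17 and 18, and Ablim1 turned to 1.14 without IgM-negative 18.

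**Figure D2:**
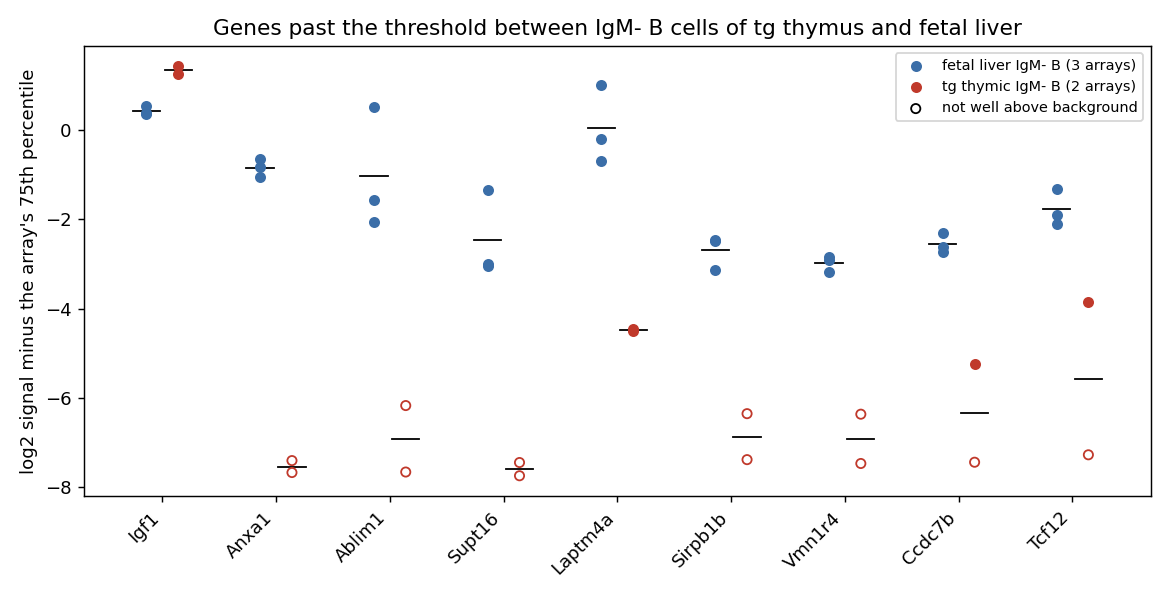
The named genes of the tg B comparison on each array (y axis, log2 signal minus the array's 75th percentile), with 3 fetal liver IgM-negative arrays in blue, 2 tg arrays in red, bars for the mean and hollow points for probes not well above background. Supt16 lay at -2.46 ± 0.97 in fetal liver and -7.60 ± 0.21 in tg cells, where its points are hollow.

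Whether the tg effect differed between DP and B cells was tested directly, although the reference groups are different tissues and the labels do not say whether tg DP and tg B cells came from the same transgenic line. As measured, Supt16 differed by 6.37 ± 0.81 (adjusted p = 0.011), with 1.23 in DP (4 against 3 arrays) and -5.14 in B cells (2 against 3). The probe A_55_P1981455, which has no gene symbol and was named after its value was seen, differed by 4.90 ± 0.71 (adjusted p = 0.0345), with 0.32 in DP and -4.58 in B cells. Neither probe was well above background on a tg B array, so only bounds hold: differences of at least 4.06 for Supt16 and 4.0 for A_55_P1981455, and falls in B cells of at least 7.1-fold and 12.8-fold. These were the 2 genes called, none of the 35 lists passed, and 3246 genes had an unadjusted p under 0.05. The median of all genes was 0.13 (-0.12 with median scaling, 0.02 with quantile scaling, 0.03 with normexp). No gene was called with normexp, array weights or slide as a block, where Supt16 differed by 6.33 ± 0.83 (adjusted p = 0.0516). The count was 3206 without tg B 22, 5 without tg B 23, 6 without wt DP 3, 3 without wt DP 2 or IgM-negative 17, and 1 without wt DP 3A, tg DP 4, tg DP 6A, IgM-negative 16 or IgM-negative 18. Without tg B 22 or tg B 23, the lone tg B array is assumed to vary like the other groups.

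IgM-positive and IgM-negative B cells of fetal liver (3 arrays each) differ in whether a complete receptor is on the surface. MHC class II genes rose as a list in IgM-positive cells, with 8 of 10 members higher (median 0.25, adjusted p = 0.0302). Its adjusted p was 0.109 with an estimated correlation. The invariant chain Cd74 was at 0.58 ± 0.31 (0.69 ± 0.70 against 0.12 ± 0.19), H2-Oa at 0.76 ± 0.50, H2-DMb1 at 0.81 ± 0.71 and H2-Eb1 at 0.23 ± 0.21. Recombination machinery had 10 of 12 members lower without passing (adjusted p = 0.566). Rag1 was at -1.33 ± 0.66, Rag2 at -3.49 ± 1.49 and Lig4 at -2.06 ± 0.78. Rag1 was lower on all 3 IgM-positive arrays than on any IgM-negative array. Pro-B and pre-B genes had 15 of 20 lower (adjusted p = 0.903), with Erg at -4.77 ± 1.65. Antigen receptor loci (adjusted p = 0.982, test upward with a median of -0.05) held Igkc, the kappa light chain gene, at 0.89 ± 0.60, higher on all 3 arrays, and Trac, at least 5.0-fold lower (-6.86 ± 0.95 against -3.27 ± 0.59). Maturation genes had 13 of 19 lower (adjusted p = 0.982, test upward with a median of -0.08), with the migration receptor Gpr183 at -1.58 ± 0.59. No gene passed in limma (smallest adjusted p = 0.0655; 2384 with an unadjusted p under 0.05), against 7 with slide as a block, 3 with median scaling, 3 with the lowest-GC probe, and 1 with array weights and 1 without the arrays that stand apart. The median of all genes was -0.15 (0.00 with median scaling, -0.04 with quantile scaling, -0.09 with normexp). On slide 4 the MHC class II mean was 0.03 in 2 IgM-positive arrays and -0.44 in 3 IgM-negative arrays. With slide as a block its median was 0.49 (adjusted p = 0.0202). The list was lost without IgM-negative 17 (adjusted p = 0.126), IgM-negative 18 (0.125), IgM-positive 20 (0.46) or IgM-positive 21 (0.204), and with quantile scaling (0.182), median scaling (0.0923) or the lowest-GC probe (0.114). Of genes, 8 were called without IgM-positive 20, 2 without IgM-positive 19 and 1 without IgM-negative 18.

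DP cells were compared with DN3 cells (3 arrays each), an earlier stage. Ribosomal protein genes fell as a list, with 22 of 24 members lower in DP (median -0.46, adjusted p = 1.0e-10, and adjusted p = 3.0e-05 with an estimated correlation). Rps9 (chromosome 7, 3658287 to 3658346, mm9) was at -1.59 ± 0.34 (-0.15 ± 0.40 against 1.44 ± 0.40), Rpl4 at -1.13 ± 0.37 and Rplp0 at -0.90 ± 0.37. MHC class I presentation genes fell, with 10 of 12 lower (median -0.46, adjusted p = 1.8e-04, and 0.0206 as the adjusted p with an estimated correlation). B2m, the shared light chain, was at -3.31 ± 1.34 and the immunoproteasome subunit Psmb8 at -2.00 ± 0.64. T lineage genes fell, with 15 of 20 lower (median -0.52, adjusted p = 6.7e-05, and adjusted p = 0.0703 with an estimated correlation). Cd3g was at -1.10 ± 0.36 and Tcf7 at -1.78 ± 1.05. Recombination machinery fell, with 10 of 12 lower (median -0.33, adjusted p = 1.8e-04, and adjusted p = 0.0928 with an estimated correlation). Rag1 was at -1.40 ± 0.66 and Lig4 at -1.88 ± 0.78. DN3 stage genes fell, with 10 of 15 lower (median -0.32, adjusted p = 0.0067, and adjusted p = 0.0703 with an estimated correlation). Dntt, the template-free polymerase of junctions, was at -0.34 ± 0.15. Notch targets and pre-TCR genes fell, with 7 of 11 lower (median -0.17, adjusted p = 0.0452, and adjusted p = 0.103 with an estimated correlation). Notch3 was at -0.61 ± 0.51 and Myc at -1.54 ± 1.28. As chosen, the Notch list shares Ptcra, Il2ra, Notch3, Dtx1, Hes1 and Tcf7 with DN3 stage and Gata3 and Tcf7 with T lineage. Recombination shares Rag1 and Dntt with DN3 stage, so these falls are not independent results. Antigen receptor loci fell, with 6 of 8 lower (median -0.19, adjusted p = 0.0241, and adjusted p = 0.198 with an estimated correlation). Trbc2 was at -1.39 ± 0.63. Glycolysis genes fell, with 14 of 20 lower (median -0.08, adjusted p = 0.0173, and adjusted p = 0.165 with an estimated correlation). The enzyme Aldoa was at -0.43 ± 0.16. Cholesterol synthesis genes fell, with 13 of 17 lower (median -0.18, adjusted p = 0.0367, and adjusted p = 0.198 with an estimated correlation). DP stage genes did not pass (9 of 16 lower, adjusted p = 0.0973). Cell cycle genes did not pass either (adjusted p = 0.799), with Kif11 at 0.50 ± 0.27 and Top2a at -1.15 ± 0.79. No single gene passed in limma (701 had an unadjusted p under 0.05), and every other setting that was run gave 0. On slide 2, where 3 DP arrays met 1 DN3 array, the list means differed by -0.37 for ribosomal, -0.61 for MHC class I, -0.26 for T lineage, -0.31 for recombination, -0.52 for DN3 stage, -0.17 for Notch, -0.11 for antigen receptor, -0.30 for glycolysis and -0.15 for cholesterol genes. With slide as a block only the ribosomal list passed (median -0.31, adjusted p = 1.6e-04), against an adjusted p of 0.110 for T lineage, MHC class I, recombination and Notch genes, 0.0719 for DN3 stage, antigen receptor and glycolysis genes and 0.695 for cholesterol synthesis. On slide 2 alone the ribosomal, MHC class I and glycolysis lists passed, while the adjusted p was 0.437 for T lineage and recombination, 0.346 for DN3 stage, 0.543 for Notch, 0.560 for antigen receptor and 0.819 for cholesterol genes. The lowest-GC probe gave 0.0531 for DN3 stage and 0.112 for cholesterol genes. Leaving out DP 3A gave adjusted p = 0.0971 for Notch, 0.165 for antigen receptor and 0.0706 for glycolysis genes. Without DP 2 it was 0.056 for Notch and cholesterol genes, and without DP 3 it was 0.101 for Notch and DN3 stage, 0.0798 for glycolysis and 0.155 for cholesterol genes, while 1 list outside these 9 passed. Leaving out DN3 7 gave 0.0587 for glycolysis genes, DN3 8 gave 0.181 for Notch, antigen receptor and cholesterol genes, and DN3 9 gave 0.132 for Notch and cholesterol and 0.312 for glycolysis genes.

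SP4 cells were compared with DP cells (3 arrays each), the step at which CD4 cells are selected. Ribosomal protein genes rose in SP4, with 20 of 24 higher (median 0.35, adjusted p = 1.7e-07, and adjusted p = 2.6e-04 with an estimated correlation). Adjusted over the list alone, 3 of them passed. Rps9 was at 1.97 ± 0.34 (1.83 ± 0.30 against -0.15 ± 0.40, adjusted p = 0.0769) and Rplp0 at 1.42 ± 0.37. T lineage genes rose, with 14 of 20 higher (median 0.31, adjusted p = 0.0076, and adjusted p = 0.215 with an estimated correlation). Gata3, which directs CD4 cell development (chromosome 2, 9779551 to 9779610, mm9), was at 2.21 ± 0.51 (-1.72 ± 0.72 against -3.93 ± 0.76) and passed only when adjusted over the list alone. Satb1 was at 2.20 ± 1.14. Antigen receptor loci rose, with 6 of 8 higher (median 0.50, adjusted p = 0.0091, and adjusted p = 0.199 with an estimated correlation). Trac was at 2.58 ± 1.17 and Tcra at 0.50 ± 0.16. MHC class I presentation genes rose, with 10 of 12 higher (median 0.23, adjusted p = 0.0066, and adjusted p = 0.088 with an estimated correlation). B2m was at 3.90 ± 1.34 and Psmb8 at 1.75 ± 0.64. Genes of TCR signal and positive selection rose, with 16 of 20 higher (median 0.21, adjusted p = 0.0491, and adjusted p = 0.175 with an estimated correlation). Nfatc1 was at 1.10 ± 0.42 but Egr3 at -0.89 ± 0.36. Mature T cell and egress genes rose, with 12 of 19 higher (median 0.25, adjusted p = 0.0491, and adjusted p = 0.215 with an estimated correlation). Il7r, the IL-7 receptor, was at 2.72 ± 1.09 and the egress receptor S1pr1 at 2.54 ± 1.29. DP stage genes (adjusted p = 0.710) and CD4 helper genes (10 of 15 higher, adjusted p = 0.210) did not pass. Rag1 was at -1.62 ± 0.66 and Ctla4 at 0.30 ± 0.24. No gene passed in limma (smallest adjusted p = 0.0645; 2183 with an unadjusted p under 0.05), against 12 with normexp, 6 with quantile scaling, 6 with the series matrix, 4 with median scaling, 2 with the trended and robust fit, 20 with array weights, 27 without the arrays that stand apart and 1 without SP4 11. No slide held both groups, so no value within a slide exists. With slide as a block, ribosomal (median 0.46, adjusted p = 0.0181, and adjusted p = 0.0703 with an estimated correlation) and antigen receptor genes (adjusted p = 0.0287) passed and the other 4 lists stood at 0.299. Without SP4 10 the adjusted p was 0.388 for TCR signal, 0.353 for mature T, 0.144 for T lineage, 0.0506 for MHC class I and 0.0724 for antigen receptor genes. Without SP4 12 these were 0.1, 0.0774, 0.118, 0.0538 and 0.0538. TCR signal was also lost without DP 3A (0.184) or DP 2 (0.151), and mature T genes without DP 2 (0.0655) or DP 3 (0.137) and with arrays sharing a title number averaged (0.0651).

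SP8 cells were compared with DP cells in the same way (3 arrays each). Ribosomal protein genes rose, with 19 of 24 higher in SP8 (median 0.23, adjusted p = 0.0060, and 0.0255 as the adjusted p with an estimated correlation). Rps9 was at 1.18 ± 0.34 (1.03 ± 0.14 against -0.15 ± 0.40) and Rpl4 at 0.70 ± 0.37. Mature T cell genes did not pass with 16 of 19 higher (adjusted p = 0.104), Il7r being at 2.42 ± 1.09. CD8 cytotoxic genes did not pass (adjusted p = 0.485), with the IL-2 receptor chain Il2rb at 0.51 ± 0.28, Dapl1 at 1.01 ± 0.55 and the killer cell receptor Klrk1 at 0.86 ± 0.55. DP stage genes had 12 of 16 lower (adjusted p = 0.363), with Rag1 at -0.77 ± 0.66. TCR signal genes had a median of -0.00 under an upward test (adjusted p = 0.797). No gene passed in limma (725 with an unadjusted p under 0.05) or in any other setting run. DP and SP8 shared no slide, and with slide as a block the ribosomal median was 0.03 (adjusted p = 0.773). Without SP8 15 the list gave adjusted p = 0.061.

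SP4 and SP8 cells were compared directly (3 arrays each). Ribosomal protein genes rose in SP4, with 16 of 24 higher (median 0.29, adjusted p = 0.0275). Its adjusted p was 0.0646 with an estimated correlation. Rplp0 was at 1.10 ± 0.37, Rps9 at 0.80 ± 0.34 and Rpl19 at 0.59 ± 0.35. CD8 cytotoxic genes had 13 of 20 lower in SP4 without passing (adjusted p = 0.432). Gzmb, a granule protease, was at -2.12 ± 0.93 (-5.36 ± 0.83 against -3.24 ± 0.42), Il2rb at -0.57 ± 0.28 and the chemokine Ccl5 at -0.37 ± 0.16. CD4 helper genes did not pass (adjusted p = 0.476), with Cd4 itself at 0.18 ± 0.15 on its brightest probe. Its other probe measured 2.26 in SP4 and 2.35 in SP8. No gene passed in limma (smallest adjusted p = 0.372; 1724 with an unadjusted p under 0.05), against 2 on 1 slide alone, 1 without the arrays that stand apart and 2 without SP4 10. On slide 3 the ribosomal mean was 1.49 in 2 SP4 arrays and 1.21 in 3 SP8 arrays. The median was 0.31 with slide as a block (adjusted p = 0.0161), and the list passed on that slide alone (adjusted p = 0.0098). It was lost without SP4 10 (adjusted p = 0.153), SP4 12 (0.0603), SP8 13 (0.205) or SP8 14 (0.172) and with quantile scaling (0.127). In turn, 4 lists passed without SP4 11 and 3 without SP8 15.

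**Figure D3:**
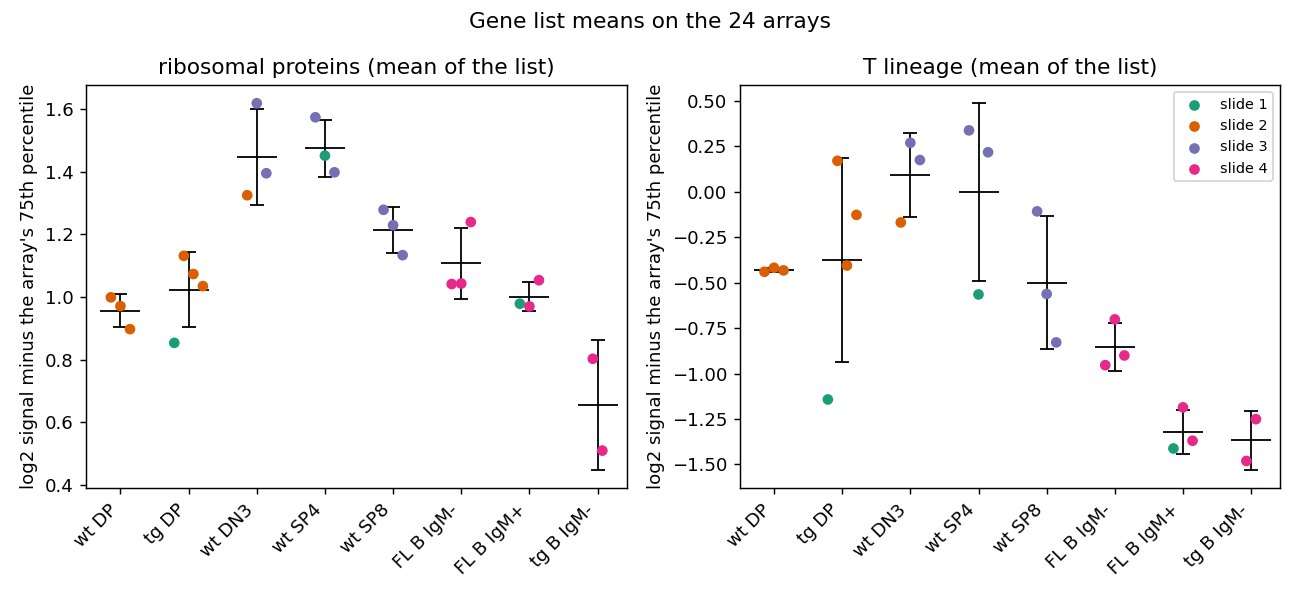
Mean of the ribosomal protein and T lineage lists on each array (y axis, log2 signal minus the array's 75th percentile) by group, with points coloured by slide and bars for the mean ± SD. The ribosomal mean was 0.96 in wt DP and 1.02 in tg DP against 1.45 in DN3, 1.47 in SP4 and 1.21 in SP8.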

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

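The tests of probe base content, of ribosomal probe GC content for DP against SP4, of the signal of the DP arrays, of T cells in the tg B sort and of the slide for DP against DN3 were chosen only after the results had been seen, as was the T against B comparison; the other tests in this part were written down beforehand.

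In 5 of 45 series of 4 tg DP values tested for a sample far from the others, 1 array stood apart, where chance gives about 1 in 20. That rate assumes 4 separate samples and unrelated series. Arrays 6, 6A and 6B may be repeats, and the series include lists as well as genes in them, so it may not hold. The receptor chain Cd247 was at -0.0068 on array 6 against -1.44 to -1.29 on the others, and Cxcl12 at -0.55 on array 6 against -1.14 to -1.05. On array 4, the kinase Blk was at -1.16 against -0.81 to -0.78 and Il2rg at -7.72, not well above background, against -2.51 to -1.84. The Notch target Heyl was at -3.18 on array 6A against -4.81 to -4.60. As measured, the tg effect on Supt16 differed between DP and B cells by 6.37, with -4.21 to -3.20 in wt DP, -3.33 to -1.43 in tg DP, -3.04 to -1.34 in fetal liver B and -7.75 and -7.45 in tg B arrays. Its probe was not well above background there, so only a difference of at least 4.06 holds, and it was not called with slide as a block (adjusted p = 0.0516), normexp or array weights. The probe A_55_P1981455 differed by 4.90, with -2.79 to -1.87, -2.97 to -0.67, -1.85 to -1.49, and -6.43 and -5.96 in the same order (at least 4.0, as tg B was not well above background).

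Some label genes differed little between cell types, with group means of 3.39 to 3.79 for Cd4 and 0.46 to 0.84 for Cd3e, B cells included, while group means of Trbc2 differed by up to 3.37. Those of Cd79a differed by up to 3.63, but between IgM-negative B cells of fetal liver (0.34) and of tg thymus (-3.29). Between wt thymocytes and fetal liver B cells Cd79a differed by -1.49. Background hybridisation that follows base content may contribute, since GC content explained 26.4% of the variance of mean signal across probes, and 94.5% of 1200 olfactory receptor probes were well above background on most arrays (93.8% of all probes). Unspliced product or genomic DNA stays open: probes on an unbroken stretch were brighter than junction probes of equal GC content by 0.605 (0.381 to 0.834 over arrays), between the bounds set in advance, although by 0.485, under the lower bound, for probes named by accession. Arrays of the wrong lineage stay open as well, as 5 of 24 (tg DP 4, IgM-negative 16, 17 and 18 and IgM-positive 19) scored on the side of the other lineage, again between the bounds. Trbc2 followed the labels (-1.22 to -0.07 on the 6 fetal liver arrays against 0.99 to 3.33 on the 12 wt thymocyte arrays). So did the brightest Tcf7 probe (-7.47 to -3.45 against -3.33 to 1.68), but its other probe did not (-7.31 on SP8 15, -4.06 on IgM-negative 16). The B lineage means of IgM-negative 16, 17 and 18 (-0.68, -0.70 and -0.07) lay above every wt thymocyte array (highest -0.88). That of IgM-positive 19 (-1.02) did not. Trac (-7.50 to -2.62 against -4.99 to -0.05) and Cd79a (-2.46 to 1.27 against -3.22 to -1.05) overlapped, and the lineage means of the other Cd79a probe differed by 0.06. The array tg DP 4 lay between for Trbc2 (0.24) and the brightest Tcf7 probe (-3.35) and low for Trac (-7.53). Its other Tcf7 probe (-2.68) lay above the 6 fetal liver arrays, and its Cd79a (-1.67) lay within both ranges. Its B lineage mean (-1.74) was below every fetal liver and wt thymocyte array. Its T lineage mean (-1.14) was below every wt thymocyte array and within the fetal liver range. A true likeness of the cells was not tested.

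Ribosomal protein transcripts were lower in DP than in DN3 and SP4, with list means of 0.90 to 1.0 on DP arrays, 1.32 to 1.62 on DN3 arrays and 1.40 to 1.57 on SP4 arrays. Probe GC content was excluded, since 0% of 10000 random lists matched on GC content and signal had a median as low for DP minus DN3 (-0.46, against a central range of -0.04 to 0.11) or for DP minus SP4 (-0.35, against -0.07 to 0.16). The share of probes well above background was 94.2% to 94.9% on DP arrays, within the 90.6% to 95.1% of DN3 and SP4 arrays. Most probes reached that mark, olfactory receptors included, so this does not exclude lower signal over background on the DP arrays. For DP against DN3 the list passed with slide as a block (adjusted p = 1.6e-04, and 0.0073 with an estimated correlation). Its median was -0.31 there against -0.46, and on the DP slide alone the means differed by -0.37 of -0.49. These values argue against the slide as the whole cause but do not exclude it, since DN3 7 was the only DN3 array on that slide. For both comparisons together the slide stays open, because the DN3 array on the DP slide lay below the other DN3 arrays by 37.1% of the difference. Moreover, SP4 and wt DP share no slide (adjusted p = 0.0181 with slide as a block, 0.0703 with an estimated correlation as well). That DP cells hold less ribosomal protein mRNA than DN3 and SP4 cells is a hypothesis that these tests leave open. SP8 against DP, where the list did not pass with slide as a block (adjusted p = 0.773), was not part of them.

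Of the 48 genes called between tg thymic and fetal liver IgM-negative B cells, 42 fell, and tg B 23 had the lowest signal of all arrays. T cells in the tg B sort, which was made by flow cytometry for IgM-negative B cells, were tested as the source of the called genes as a set. Of the called genes, 97.9% (47) lay outside the range of fetal liver B cells and the 4 wt thymocyte groups by more than 2 SE (median distance 2.01). As measured, these levels are not those of a mixture, which would lie between. The genes were called from the same tg B values, however, which favours levels outside that range, so T cells in the sort are not excluded. Trbc2, bright in thymocytes, differed by -0.20 ± 0.71, and the T lineage list, which shares Gata3, Tcf7, Themis and Cd5 with other lists, had a median of -0.46. For Tcf7 a second probe was at -1.77 in tg B against -5.99 in fetal liver cells, where only IgM-negative 16 was well above background. The brightest Tcf7 probe was at -5.32 in tg B, with only tg B 22 well above background, against -4.23. Low signal of tg B 23 stays open: without it the genes kept 78.3% of their median size (2.12 against 2.71), 3 of 48 stayed past the threshold and 48 of 48 kept their direction, while without tg B 22 all 48 stayed past it (119% of the size, 3.24); tissue, age and genotype, which differ together here, stay open too and were not tested apart.

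Other splits of the samples were compared with the real one. For tg against wt DP, 9 of 35 gave as many lists (1, highest other 4) and 16 of 35 as many signatures (1, highest other 1), so chance is not excluded for these. These splits treat arrays that share a title number as separate samples, although they may be repeats, and move tg DP 4 across slides. Its gene count was 0, which fixes the outcome (35 of 35 as large, highest other 0) and decides nothing. For T against fetal liver B, 1 of 100 splits, the real one, gave as many genes (82, highest other 2). The other splits exchange single arrays and break up the sorted groups, which the real one keeps whole, so they do not exclude chance. They do not exclude the slide either, since slides nearly follow lineage and the splits cross them. With slide as a random block the count was 0, as it was without IgM-negative 16, IgM-negative 18 or IgM-positive 21. For its lists chance is not excluded (9 of 100 as many, 3 against a highest other of 5). IgM-positive against IgM-negative, DP against DN3, SP4 and SP8 against DP, and SP4 against SP8 have 10 splits each, too few for a share under 0.05. Their gene counts were 0 in the real split and in the highest other split (10 of 10 as large), which decides nothing. Their list counts were 1 against 1 for IgM-positive against IgM-negative and for SP4 against SP8 (2 of 10 as large each), 9 against 6 for DP against DN3, 6 against 4 for SP4 against DP and 1 against 0 for SP8 against DP (1 of 10 each). No splits were run for tg B against fetal liver B or for the difference of the tg effects.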

How the results depend on the processing

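Array weights, leaving out the 3 arrays that stand apart, single probes, the lowest-GC probe, 1 slide alone and everything about T against B were chosen after seeing the data. Counts below are genes unless lists are named, and the cause of each change was not tested unless stated. Called named genes (21 results, 536 values) kept direction and side in 283 values, kept only direction in 249 and reversed in 4. Genes not called (265 results, 5692 values) were alike in 5487, passed in 28 and moved in 177, with 251 changes of sign in 95 of them. The ribosomal list kept its call for DP against DN3 in 15 of 15 settings (adjusted p = 1.1e-11 to 3.6e-04) and for SP4 against DP in 14 of 14 (5.4e-08 to 0.0181). No list that passed reversed under normexp, quantile or median scaling. No paired analysis was run: the title numbers run on from group to group and do not give the donor, so possible pairing between groups is unknown.

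Normexp gave 10 for tg B against fetal liver B, 12 for SP4 against DP, 0 for the difference of the tg effects and 185 for T against B, and 2 lists each for tg against wt DP, SP4 against SP8 and the difference. Quantile scaling gave 11, 6, 1 and 141 in the same order, 2 lists for tg B and for the difference, 0 lists for IgM-positive against IgM-negative and for SP4 against SP8, and adjusted p = 0.0019 for genes lower in DN3 in tg DP. The series matrix gave 11, 6, 1 and 142. Median scaling gave 14 for tg B, 3 for IgM, 4 for SP4 against DP and 50 for T against B, with 0 lists for IgM. Without the filter tg B gave 12, and 1 array was closest to its own group; the filter on 2 arrays gave tg B 12.

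Slide as a fixed block gave 7 for IgM, 0 for the difference and 32 for T against B. Lists were 2 for tg against wt DP, 1 for DP against DN3, 2 for SP4 against DP, 0 for SP8 against DP, 5 for SP4 against SP8 and 0 for T against B. There the T lineage list reversed (adjusted p = 0.970, range over settings 0.0013 to 0.970) and Tnfrsf22 reversed to 0.11. Slide as a random block (correlation 0.0514) gave T against B 0. Compared groups only gave 0 for tg B, 4 for the difference and 210 for T against B. The trended and robust fit gave 103 for tg B, 2 for SP4 against DP, 4 for the difference and 488 for T against B. The mean of probes gave 22 for tg B and 5 for T against B, a 2-fold minimum 23 for T against B, and averaging shared title numbers 1 for the difference, 2 for T against B and 0 lists for tg against wt DP.

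Array weights gave 7 for tg against wt DP, 0 for tg B, 1 for IgM, 20 for SP4 against DP, 0 for the difference and 146 for T against B. Without the 3 arrays that stand apart, counts were 7 for tg B, 1 for IgM, 27 for SP4 against DP, 1 for SP4 against SP8 and 196 for T against B, and lists 4 for tg against wt DP, 1 for tg B, 0 for IgM and 2 for the difference. Testing each probe gave 14 for tg B and 17 for T against B. The lowest-GC probe gave 13 for tg B, 3 for IgM and 8 for T against B, and lists 0 for tg against wt DP, 0 for IgM, 2 for SP8 against DP and 0 for SP4 against SP8. Arrays of 1 slide gave 0 for tg B and 2 for SP4 against SP8, and 3 lists each for tg against wt DP, DP against DN3 and SP4 against SP8. On that slide Ablim1 and Ccdc7b reversed to 1.05 each, and Ablim1 ranged from -6.64 to 1.14 over left-out arrays, reversing without IgM-negative 18, because another probe became the brightest. An estimated correlation left 0 lists for tg against wt DP, 0 for IgM, 2 for DP against DN3, 1 for SP4 against DP, 0 for SP4 against SP8 and 1 for T against B, and signature values of 0.591, 0.204 and 0.344. With 400 genes, those lower in T cells gave adjusted p = 0.0847 in tg B.

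Leaving out each array in turn gave 0 to 0 genes for tg against wt DP, DP against DN3 and SP8 against DP, 6 to 5855 for tg B, 0 to 8 for IgM, 0 to 1 for SP4 against DP, 0 to 2 for SP4 against SP8, 1 to 3206 for the difference and 0 to 367 for T against B. Lists ranged from 0 to 3 for tg against wt DP, 0 to 1 for tg B, 0 to 1 for IgM, 6 to 9 for DP against DN3, 1 to 7 for SP4 against DP, 0 to 1 for SP8 against DP, 0 to 4 for SP4 against SP8, 0 to 1 for the difference and 2 to 4 for T against B. The arrays behind these extremes stand with each comparison: 5855 and 3206 came without tg B 22, 6 without IgM-negative 17, 367 without IgM-positive 19, 8 without IgM-positive 20, 1 in SP4 against DP without SP4 11 and 2 without SP4 10.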

Other observations

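The genes named in this part were chosen after their values were seen. Of the 35 lists, 22 passed in no comparison. In tg B cells (2 arrays) against fetal liver IgM-negative cells (3 arrays), where the median of all genes was -0.21 and tg B 23 had the lowest signal, p53 target and apoptosis genes did not pass (13 of 14 lower, median -0.51, adjusted p = 0.329). Bcl2l11, which promotes cell death, was at -4.36 (adjusted p = 0.0669, well above background on 1 of 2 tg arrays) and Pmaip1 at least 1.6-fold lower (-6.65 against -4.60, adjusted p = 0.252). Interferon response genes had 22 of 27 lower there (median -0.48, adjusted p = 0.50), with the interferon regulator Irf7 at -1.73 and Ifit2 at -1.64. In the difference of the tg effects they had a median of 0.60 with 20 of 27 higher (adjusted p = 0.386). In IgM-positive against IgM-negative fetal liver cells (3 arrays each), 12 of 14 NF-kB response genes were lower (median -0.46, adjusted p = 0.318), with the adhesion molecule Icam1 at -2.99 (well above background on 2 of 3 IgM-positive arrays) and the activation marker Cd83 at -1.44. From DN3 to DP (3 arrays each), immediate early genes had a median of -0.12 (adjusted p = 0.0682), with Fos at -1.91. Glucocorticoid response genes had a median of -0.18 (adjusted p = 0.181), with Klf9 at -1.0. Cell cycle genes came closest to passing in SP4 against DP (3 arrays each), with 22 of 30 lower (median -0.16, adjusted p = 0.591). The replication helicase gene Mcm2 was at least 1.6-fold lower (-7.47, not well above background, against -4.68 ± 1.95, where 2 of 3 arrays were). Top2a was at 1.15.

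Lists of other cells that a sort could carry over passed in no comparison (8 of 8). The lowest adjusted p of each was 0.211 for megakaryocyte and mast genes (SP4 against DP, median -0.42, 6 of 8 lower), 0.386 for hepatocyte genes (difference of the tg effects, median 0.25), 0.399 for NK and gamma delta T genes (DP against DN3) and 0.485 for myeloid genes (SP8 against DP). It was 0.629 for thymic epithelium and for dendritic cells (SP4 against SP8), 0.647 for erythroid genes (tg against wt DP, 17 of 20 lower, median -0.11) and 0.689 for mesenchyme and endothelium (DP against DN3). Hepatocyte genes, from the tissue around fetal liver B cells, had 14 of 16 members lower in tg B than in fetal liver cells (median -0.32, adjusted p = 0.50), with the fibrinogen chain Fgb at -1.69, while albumin (Alb) was at 0.60 (well above background on 2 of 3 fetal liver arrays). Lists reported above for the comparison they concern had their lowest adjusted p elsewhere. Niche signal receptors reached 0.239 in DP against DN3 (8 of 12 lower) and maturation genes of IgM-positive B cells 0.354 in SP4 against SP8 (13 of 19 higher). Pro-B and pre-B genes reached 0.485 in SP8 against DP (13 of 20 lower), niche ligands 0.591 in SP4 against DP (7 of 8 lower) and fetal haematopoiesis genes 0.647 in tg against wt DP (9 of 12 lower).

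With fry, which asks only whether a list's genes move one way and does not compare them with other genes, ribosomal, p53 target and MHC class I genes moved down in tg B cells (adjusted p = 9.4e-04, 9.4e-04 and 0.0049), where the median of all genes was -0.21 as well. In T against fetal liver B, fry gave T lineage up (adjusted p = 0.0161) and MHC class II down (adjusted p = 0.0054), and ribosomal genes up (adjusted p = 0.0054), which camera did not call (adjusted p = 0.206). Elsewhere fry passed 2 lists for the difference of the tg effects, 1 for DP against DN3 (9 with camera), 1 for SP4 against DP (6 with camera) and 0 for each other comparison.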
